A study of Mus musculus with 2 samples.

How the data were processed

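H3K36me3 ChIP-seq, in which DNA bound to histone H3 trimethylated at lysine 36 is immunoprecipitated and sequenced, was analysed in hindbrain of mouse embryos at embryonic day 10.5. The 2 libraries were biological replicates of a single group, per the labels. Replicate 1 was made from a pool of 69 embryos and replicate 2 from a pool of 51, both of strain B6NCrl and of both sexes, with fragments of 300 to 500 bp. The labels name no second condition, so the comparisons were replicate against replicate, and the peaks against the genome annotation.

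The values used here start at the authors' peak lists on mouse assembly mm10, per the file headers. Each replicate's list was derived from that replicate's filtered alignments, per the text files deposited beside the lists. A pooled list was derived from the alignments of both replicates together, and a replicated list was derived from the pooled list and both replicates' lists. The aligner, the peak caller, its version, its threshold and the rule for calling a peak replicated are not given in the sources used here. Each peak carries the authors' enrichment signal and the authors' −log10 p and −log10 q, in the columns of the narrowPeak format. These deposited signal and −log10 values belong to the caller's own run on each list, so they were used only to rank, filter or describe peaks within that list. All 132735 replicated peaks were also entries of the pooled list. The lowest −log10 p was 2.00 in replicate 1 and 2.03 in replicate 2. Read counts are not in the peak lists, so the depth of each library is unknown here and no interval that needs a depth is given. A base outside the peaks is a base at which no peak was called, which depends on the depth and the caller's threshold. No control library was analysed here.

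Peaks on chromosomes 1 to 19, X and Y were used. Overlapping peaks of a list were merged before bases were counted. Genes were taken from GENCODE release M21 (Ensembl release 96), whose assembly, GRCm38, has the coordinates of mm10. All peaks of the 4 lists ended within the GRCm38 chromosomes. The 21911 protein-coding symbols were each given 1 gene body, the longest where a symbol occurred more than once. The covered percent of a gene is the share of its annotated body, introns included, that lies in the merged peaks of a list. A gene was called marked when at least 25% of its body was covered by the replicated list. Values per replicate come from each replicate's own list, and means are given with the SD of the 2 replicates. Where gene bodies overlap, a peak counts for each of them.

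The overlap of the replicates was the percent of peaks with at least 50% of their own length in the other replicate's merged peaks, and the Jaccard index in bases. Both were set against 100 circular shifts of the other list along its chromosomes (one-sided permutation test, smallest possible p = 0.0099). The genic location of covered bases was set against 100 circular shifts of the peaks (two-sided permutation test, smallest possible p = 0.0198). Promoters were the bases within 1 kb of a protein-coding gene start. Profiles used marked genes of at least 10 kb, in 20 equal parts of the body and 10 kb on each side. Genes are not replicates, so profiles carry no p. Domains were replicated peaks joined over gaps of up to 3 kb.

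The 31 gene lists and the rule for naming genes were fixed before the data were examined. The members came from textbook knowledge of the tissue, of the other cell types it could hold and of gene families. Members were matched among protein-coding genes, except in the list of imprinted lncRNA units, which was matched among all genes. By this rule 9 symbols were not matched, 8 of them in the imprinted list, whose non-coding members were thereby left out. A list's median covered percent was set against 10000 random lists of protein-coding genes matched in 20 bins of gene length (two-sided permutation test). Benjamini-Hochberg adjustment ran over the 31 lists, and a list was called only when its adjusted p was under 0.05 in both replicates. Such a p describes these libraries and compares a list with other genes, not a condition with another. Genes were named by these parts of the rule. They were the 8 genes of at least 10 kb with the highest covered percent, the 5 genes with the most covered bases, the 5 genes of at least 10 kb with the largest replicate difference, the 2 highest and 2 lowest members of at least 2 kb in each list, 10 genes written down in advance, and the genes of the 5 longest domains. Genes beside or within the domains outside genes, and 4 Y-linked genes, are outside this rule and were chosen after the domains and the X-linked values were seen.

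The genic location, overlap and list median tests were tested on simulated data, and the other permutation tests were not. The simulated peaks had replicate 1's widths and were placed at random, so the clustering of the real peaks was not kept. With 0, 30 and 60% of these simulated peaks moved into gene bodies the genic permutation test gave p = 0.317, 0.0198 and 0.0198. With 50 and 90% of peaks kept in a simulated partner, the measured overlap was 52.7 and 90.6%, and it was 5.54% with none kept. Among 100 simulated lists of 20 genes, 2 had an unadjusted permutation p under 0.05 with no added coverage. With 20 points added 24 had one, and with 40 points added 98. For lists of 50 genes these numbers were 4, 82 and 100. The simulation had a single set of values, so the adjustment over lists and the rule of both replicates were not tested.

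The alternatives planned before the data were examined were stricter peaks (−log10 p of at least 5, or −log10 q of at least 2), other overlap rules, equal peak numbers, random placement of peaks with bedtools in 20 draws, the pooled list, and each replicate's list alone. Also planned were other marking thresholds (10 and 50%), gene bodies without their first 1 kb, genes that overlap no other, genes of at least 5 kb, the share of marked genes in place of the median, matching on exon number in 4 bins, other gene sets for the profile, and gaps of 1 and 10 kb. Circular shifts beyond the first 3 Mb of each chromosome were added after the data were examined. The closing section gives values under these alternatives. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and bedtools 2.31.1 were used.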

Results

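H3K36me3, a histone modification that is deposited along transcribed gene bodies, was profiled by ChIP-seq in mouse hindbrain at embryonic day 10.5, a stage at which neural progenitors divide along the neural tube and the first neurons are born. The group held 2 libraries, replicate 1 from a pool of 69 embryos and replicate 2 from a pool of 51. The depth of the libraries is unknown from the peak lists. The design has 1 group, so its comparisons are between the replicates and between the marked and unmarked parts of the genome. All positions are on mm10.

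The replicates marked largely the same bases. Replicate 1 held 209603 peaks over 155 Mb and replicate 2 held 175802 peaks over 168 Mb, with a mean covered length of 161 Mb ± 8.54 (SD, n = 2). Peaks were narrower in replicate 1, with a median width of 347 bp against 404 bp in replicate 2. The pooled list held 210032 peaks over 183 Mb and the replicated list 132735 peaks over 167 Mb. Of the peaks of replicate 1, 71.0% had at least 50% of their length in peaks of replicate 2, against 6.70% on average after circular shifts (p = 0.0099, one-sided permutation test with 100 shifts, the smallest p it can give). In the other direction the share was 63.7% against 6.15% after shifts (p = 0.0099, same permutation test). When 50% of both peaks had to overlap, the shares were 36.7 and 43.8% (p = 0.0099 for each, same permutation test). Peaks with −log10 p of at least 5 numbered 129186 in replicate 1 and 115671 in replicate 2. In bases, 85.5% of replicate 1's covered length lay in replicate 2's peaks and 79.4% of replicate 2's in replicate 1's, a Jaccard index of 0.6998 against 0.0336 after shifts.

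Sharing followed peak strength. In 10 equal groups of replicate 1's peaks ranked by the authors' −log10 p, 38.5% of the weakest group were shared, with a median width of 196 bp, and 99.99% of the strongest group were shared, with a median width of 2322.5 bp. In replicate 2 the corresponding shares were 31.6% and 99.8%. The score ranks peaks only within a list, and no test was made across these groups.

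**Figure D1:**
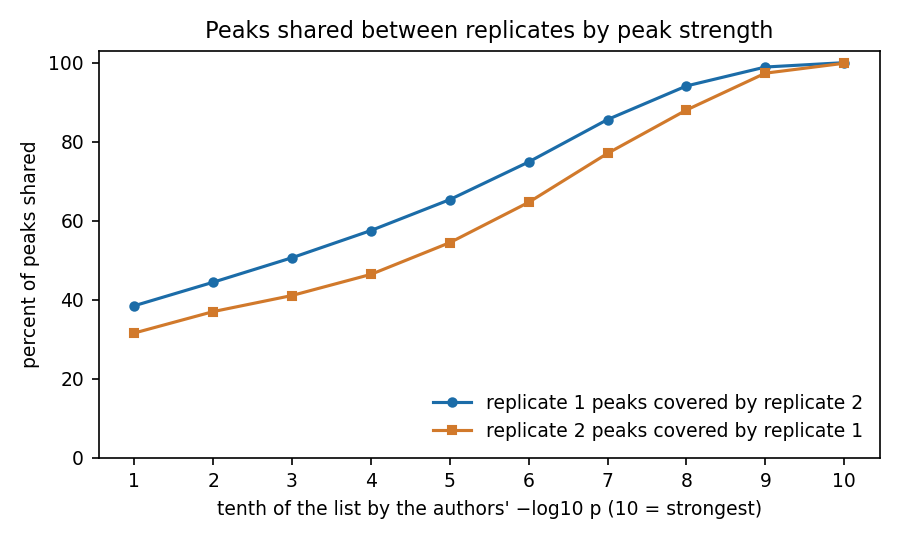
Percent of each replicate's peaks with at least 50% of their length in the other replicate's peaks (y axis), in 10 equal groups of the list ranked by the authors' −log10 p (x axis, 10 the strongest). Circles are replicate 1 peaks and squares replicate 2 peaks, and the shares rise from 38.5 and 31.6% in the weakest group to 99.99 and 99.8% in the strongest.

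The mark lay in protein-coding genes. In the mean of the replicates 94.0% ± 0.0368 (SD, n = 2) of covered bases fell inside protein-coding gene bodies, against 40.2% in both replicates after circular shifts. This was 2.33-fold in replicate 1 and 2.34-fold in replicate 2 (p = 0.0198 in each, two-sided permutation test, the smallest p it can give). Exons held 20.7% ± 0.469 of covered bases, 5.56-fold and 5.39-fold the shifted value in the 2 replicates, and introns held 73.3% ± 0.506, 2.00-fold and 2.02-fold (p = 0.0198 for each, same permutation test). Promoters were depleted, with 0.465% ± 0.00374 of covered bases, 0.290-fold and 0.287-fold the shifted value. Bases outside any annotated gene made up 4.81% ± 0.0712 of the covered length, against 53.0% after shifts in both replicates (p = 0.0198 for promoters and for bases outside genes, same permutation test). With 20 random placements in place of shifts the folds for the replicated list were 2.31 and 0.0899 in gene bodies and outside genes, with p = 0.0952, the smallest p that so few permutation draws can give.

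Along marked genes the coverage was lowest at the start and highest towards the end. Over 5653 marked genes of at least 10 kb, the first of 20 equal parts of the gene body was covered to 5.22% ± 0.791 (SD, n = 2) and the 18th part to 76.7% ± 2.04. Coverage was 69.8% ± 2.87 in the last part and fell to 49.9% ± 1.97 in the 2 kb after the annotated end and to 27.6% ± 1.19 in the next 2 kb. The 2 kb before the start held 3.99% ± 0.419. The first covered base lay at a median of 2713 bp from the start in replicate 1 and 2577 bp in replicate 2. The downstream 50% of the gene body was more covered than the upstream 50% in 87.9% ± 0.100 of these genes, with median coverages of 77.2% ± 4.12 and 45.9% ± 3.89.

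**Figure D2:**
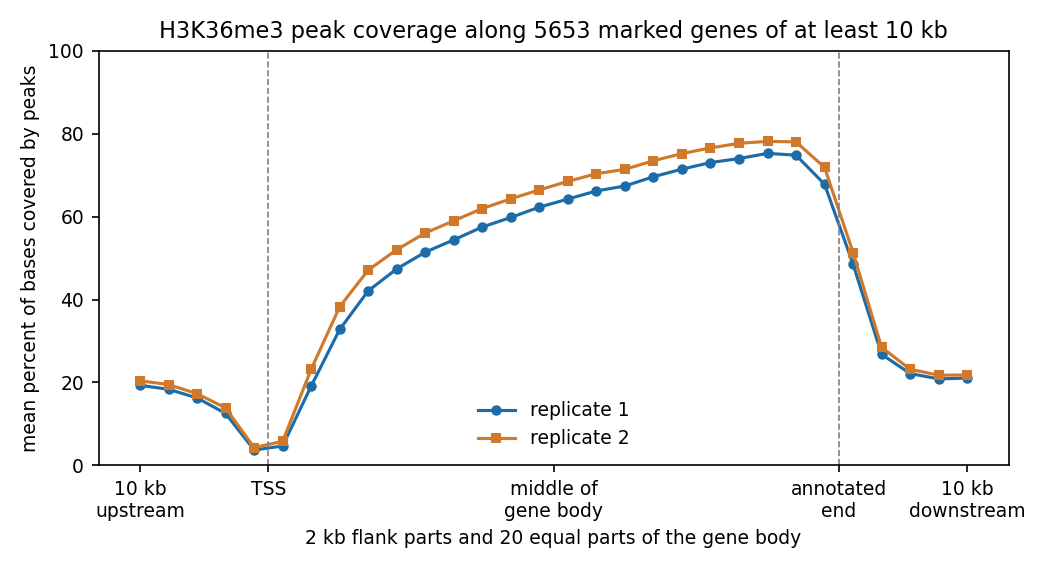
Mean percent of bases covered by peaks (y axis) in 20 equal parts of the gene body and in 2 kb parts of the 10 kb on either side (x axis), over 5653 marked genes of at least 10 kb. Circles are replicate 1 and squares replicate 2, and dashed lines mark the gene start and annotated end. Coverage rises from 4.66 and 5.78% in the first part to 75.3 and 78.1% in the 18th.

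Of 21911 protein-coding genes, 7663 (35.0%) were marked in the replicated list. Each replicate's own list marked 7536.5 genes ± 134 (SD, n = 2), 7442 in replicate 1 and 7631 in replicate 2, and 7255 were marked in both. At thresholds of 10 and 50% of the gene body, 9276 and 5167 genes were marked. No base was covered in either replicate in 9397 genes (42.9%). In 4 equal groups of gene length, 21.9% of genes of up to 6526 bp were marked, 40.7% of those from 6527 to 17433 bp, 47.1% of those from 17441 to 45168 bp and 30.2% of those of 45201 bp or more.

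The genes of at least 10 kb with the highest coverage in the replicated list included splicing factors, a chromatin adaptor and a cadherin. 1700109H08Rik (chromosome 5, 3571566 to 3584356) was covered in full in that list, with 98.6% ± 1.94 (SD, n = 2) in the mean of the replicates' own lists, and its body overlaps another protein-coding gene. Celsr2, a seven-pass transmembrane cadherin of planar cell polarity, had 95.5% ± 1.48 on chromosome 3 (108390851 to 108415552). Rbm39 and Sf3a1, both splicing factors, had 95.5% ± 1.95 and 95.2% ± 0.723, Trrap, an adaptor of histone acetyltransferase complexes, had 95.9% ± 1.10, and Gtf3c1, a subunit of the RNA polymerase III factor TFIIIC, had 95.1% ± 1.28. Mn1 had 90.7% ± 3.05 and Gm42715, which overlaps another gene, 95.5% ± 2.24. In covered bases, Syne2, which encodes the nuclear envelope protein nesprin-2, held 214 kb on chromosome 12, Adgrv1 214 kb on chromosome 13 and Msi2, an RNA-binding protein of neural progenitors, 208 kb on chromosome 11. The annotated bodies of Gm20388 and Fgfr2, with 796 and 428 covered kb, span 4434.88 and 2960.9 kb and overlap other genes, so these values include the peaks of the genes within them. Setd2, the enzyme that trimethylates H3K36, was itself covered to 75.4% ± 6.80, and the H3K36 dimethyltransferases Nsd1 and Nsd2 to 86.2% ± 5.11 and 84.6% ± 7.68.

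Genes of basic cell functions, and also Zfp zinc finger genes, were covered far above other genes of the same length. Of the 31 lists, 9 had a median covered percent above length-matched random lists in both replicates. All 36 spliceosome and RNA processing genes were marked, with a median of 83.1% ± 4.37 (SD, n = 2), as were 47 of 49 cell cycle and DNA replication genes (79.2% ± 5.88), 42 of 47 chromatin modifiers (74.97% ± 5.69), 45 of 54 translation factors (71.5% ± 4.09) and 31 of 39 proteasome subunits (68.9% ± 3.16). Among ribosomal protein genes 76 of 83 were marked (62.7% ± 2.91), among nuclear genes of the respiratory chain 69 of 82 (52.5% ± 3.93), and among Zfp zinc finger genes 259 of 391 (40.8% ± 1.95). Matched lists had medians from 0 to 10.5% for these lists in replicate 1. The largest adjusted p of these 8 lists was 7.75e-04 in either replicate, from the smallest p that 10000 permutation lists can give (2e-04).

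Single members of these lists ranged widely. Sf3b3, a subunit of the U2 snRNP, had 95.6% ± 0.849 (SD, n = 2), Chd4, the ATPase of the NuRD complex, 95.4% ± 0.325, Top2a, the topoisomerase of dividing cells, 93.8% ± 1.152, the replicative helicase subunit Mcm5 93.1% ± 2.60, and the translation factors Eif4g2 and Eif3c 93.6% ± 1.21 and 93.5% ± 0.971. Zfp869 was covered in full in both replicates. Among the lowest members, 0 in both replicates was the value of the muscle ribosomal protein gene Rpl3l, the immunoproteasome subunits Psmb8 and Psmb9, the germline translation factor Eif4e1b and the respiratory chain isoform genes Cox4i2 and Cox7b2. The lowest cell cycle members were Cdk6 (0.543% ± 0.197) and the X-linked Pola1 (6.26% ± 2.89), and the lowest chromatin modifiers were the X-linked Mecp2 (12.6% ± 1.48) and Kdm6a (15.3% ± 3.33).

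Neural progenitor genes were covered above other genes of the same length. Of the 46 genes of this list 32 were marked, with a median of 36.2% ± 9.26 (SD, n = 2), 29.7% in replicate 1 and 42.8% in replicate 2, against matched medians of 0.695 and 0.310% (adjusted p = 0.00207 and 6.89e-04, permutation test). Msi1, an RNA-binding protein of neural progenitors, had 92.1% ± 1.149 and the receptor Notch3 87.5% ± 1.96. Sox2, the single-exon pluripotency and progenitor factor, had 44.5% ± 5.78 on chromosome 3 (34650405 to 34652461), while Hes3 and Zic3 had no covered base. Early neuron genes were not called, with 12 of 51 marked and a median of 7.39% ± 0.685 (adjusted p = 0.272 and 0.337, permutation test). Dpysl5, a neuronal collapsin response mediator, had 66.2% ± 4.84, Map1b, a microtubule-associated protein of growing axons, 57.9% ± 9.38, and Pou4f1 and Robo2 had none.

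Most listed regulators of hindbrain pattern were unmarked, as were most protein-coding genes, of which 35.0% were marked. Among hindbrain segment and isthmus regulators 6 of 30 were marked, led by Irx2 (53.8% ± 2.60, SD, n = 2) and Irx3 (45.5% ± 5.25). The rhombomere genes Hoxb1, Egr2, Mafb and Hoxd4 had no covered base, and Hoxa2 had 10.9% in replicate 1 and 0 in replicate 2. Among dorsoventral patterning genes 8 of 49 were marked, led by the Hedgehog receptor Ptch1 (69.6% ± 5.88) and the signal transducer Smo (47.9% ± 11.9), while Vsx2 and Wnt8b had none. None of 22 posterior Hox genes and none of 32 forebrain and midbrain regulators was marked, and Foxg1, the forebrain factor, and Tbr1 had no covered base. The medians of matched lists were 0 in replicate 2 for these 4 lists, so their medians could not be called below. By the share of marked genes, posterior Hox genes, forebrain and midbrain regulators and dorsoventral patterning genes lay below matched lists in both replicates, and hindbrain segment and isthmus regulators were not called.

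Genes of other cell types were rarely marked. None of the 25 endothelium genes, 21 erythroid genes, 38 heart and skeletal muscle genes or 33 liver genes was marked, nor any of 1092 olfactory receptors and 326 vomeronasal receptors. The 67 replication-dependent histones, a gene family and not another cell type, were also unmarked. Their median length was 539 bp, and 9.70% of genes in length-matched lists were marked in the mean of the replicates. The vessel receptors Tek and Tie1, the haemoglobin gene Hba-a1 and the liver gene Alb had no covered base. Hba-a1 is only 0.955 kb long, and short genes were marked less often than longer ones. Marked genes numbered 1 of 35 in germline and meiosis, 1 of 36 in mature neuron and synapse (Dlg4, 41.6% ± 2.32, SD, n = 2), 1 of 22 in neural crest and glial precursors (Ednrb, 45.0% ± 15.9), 3 of 22 in oligodendrocyte and astrocyte, led by Cnp (87.8% ± 1.90), which overlaps another gene, 3 of 23 in macrophage and microglia, and 2 of 30 in mesenchyme and meninges, led by Fn1, the matrix protein fibronectin (92.1% ± 2.27). None of 30 long neuronal adhesion and channel genes was marked, and the highest of them, Auts2, had 6.31% ± 0.554 of a body of 1106.01 kb. Imprinted genes had 13 of 33 members marked, led by Nnat (85.2% ± 7.75), which overlaps another gene, and Igf2r (70.5% ± 3.06), imprinted lncRNA units 5 of 10, led by Nespas (80.2% ± 2.40), which overlaps a coding gene, and clustered protocadherins 21 of 56, each of which overlaps at least 1 other coding gene.

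By its median no list was called below matched genes in both replicates, and matched medians lay between 0 and 8.42% for the 22 uncalled lists in replicate 1. With the share of marked genes in place of the median, 16 lists lay below matched lists in both replicates. They included endothelium (0% against 36% in matched lists), forebrain and midbrain regulators (0% against 34.4%), olfactory receptors (0% against 34.7%), mature neuron and synapse (2.78% against 30.6%), posterior Hox genes (0% against 29.5%) and hindbrain dorsoventral patterning (13.3% against 32.7%), and the largest adjusted p of the 16 lists was 0.0198 in either replicate (permutation test). The other lists below were erythroid, germline and meiosis, heart and skeletal muscle, liver, macrophage and microglia, mesenchyme and meninges, neural crest and glial precursors, oligodendrocyte and astrocyte, replication-dependent histones and vomeronasal receptors. Early neuron genes (20.6% against 27.5%), hindbrain segment and isthmus regulators (20% against 30%), imprinted genes, imprinted lncRNA units, clustered protocadherins and long neuronal genes were called by neither measure. By their medians, mature neuron and long neuronal genes lay below matched lists in replicate 1 (adjusted p = 0.0361 and 0.0254) but did not pass in replicate 2 (0.143 and 0.275, permutation test). By the share of marked genes, clustered protocadherins passed above matched lists in replicate 1 (37.5% against 25%) but not in replicate 2 (37.5% against 26.8%). Among genes of at least 5 kb the protocadherin median lay 37.2 points above matched lists. Bodies such as those of Pcdhgc4 and Pcdhgc5 share their end at 37841873 on chromosome 18. The same covered bases thus count for several protocadherins, and no p is given for them.

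**Figure D3:**
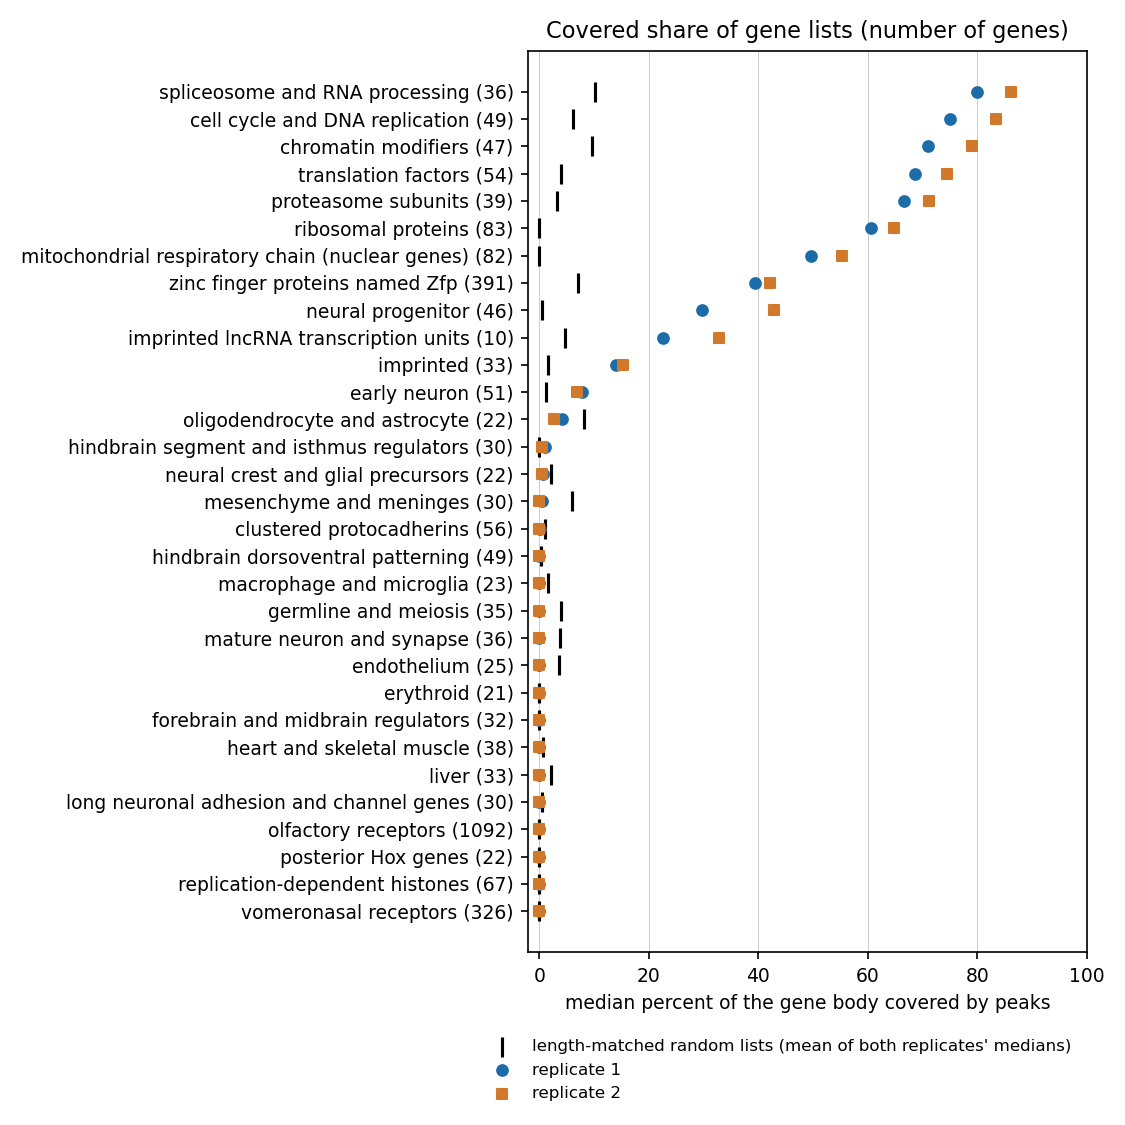
Median percent of the gene body covered by peaks (x axis) for the 31 gene lists (y axis, number of genes in brackets). Circles are replicate 1, squares replicate 2, and vertical bars the mean of both replicates' medians of length-matched random lists. The 9 called lists stand at 29.7% or more in both replicates.

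The replicates differed in how far marked genes were covered. The median covered percent of marked genes was 56.9% in replicate 1 and 61.4% in replicate 2, and 6043 of 7663 marked genes were more covered in replicate 2. The median difference, replicate 1 minus replicate 2, was -3.58 points over marked genes. The largest differences of list medians were -13.1 points for neural progenitor genes, -10.3 for the 10 imprinted lncRNA units, -8.32 for cell cycle and DNA replication and -8.05 for chromatin modifiers, and early neuron genes had 0.969. The medians of the members' own differences were smaller in size, at -8.14, -3.39, -6.18, -4.52 and 0 points for these lists in turn. Among genes of at least 10 kb the largest differences were at Ildr2 (28.7% in replicate 1 and 62.1% in replicate 2), Wnt7a, a signalling ligand (28.3 and 59.9%), Dnase2a (49.6 and 19.2%), Upf3b, an X-linked factor of nonsense-mediated decay (28.1 and 57.5%) and the kinase gene Nuak1 (38.7 and 65.7%). With 1 library on each side no test of these differences between pools was possible.

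The X chromosome was less covered by peaks than the autosomes. Its gene bodies were covered to 3.95% in replicate 1 and 4.96% in replicate 2, against 14.5 and 15.6% on the autosomes, a ratio of 0.295 in the mean of the replicates. In the replicated list 121 of 948 X-linked protein-coding genes (12.8%) were marked, against 7542 of 20780 autosomal genes (36.3%). Among autosomes the covered share of gene bodies in replicate 1 ran from 10.6% on chromosome 14 to 20.7% on chromosome 11. No gene on chromosome Y was marked. The pools held both sexes, and coverage was not corrected for the number of sex chromosomes, for depth or for the caller's threshold. No test was made between chromosomes.

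Peaks of the replicated list joined into 23885 domains over gaps of up to 3 kb. Of these, 6631 were at least 10 kb long, 697 at least 50 kb and 48 at least 100 kb, and 6561 of the domains of at least 10 kb touched a protein-coding gene. The longest, 217 kb on chromosome 4 (137993848 to 138210448), spanned 99.6% of the body of the translation factor gene Eif4g3 (137993022 to 138208508). Replicate 1's own peaks covered 76.3% of it and replicate 2's 83.7%. The next domains lay over Syne2 (195 kb, chromosome 12, 75876374 to 76071243), over Usp34 and Ahsa2 (153 kb, chromosome 11, 23344034 to 23496637), over the ubiquitin ligase gene Herc2 (152 kb, chromosome 7, 56081676 to 56233907) and over Wdfy3, an autophagy adaptor (152 kb, chromosome 5, 101830023 to 101981923).

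**Figure D4:**
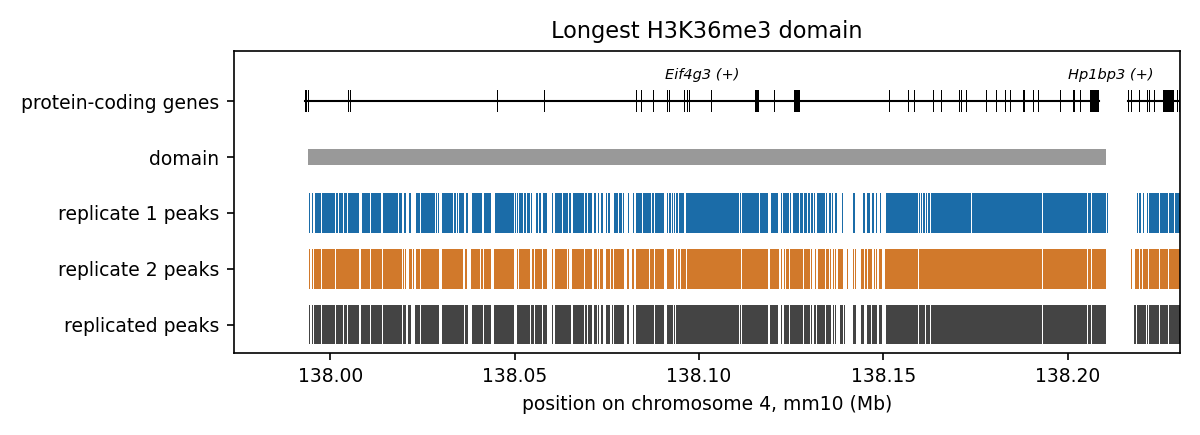
Map of the longest domain on chromosome 4 (x axis, mm10 position in Mb). Rows from the top show protein-coding genes with exons as black boxes, the domain, and the merged peaks of replicate 1, replicate 2 and the replicated list. The domain spans the body of Eif4g3, and the replicates' peaks cover 76.3 and 83.7% of its length.

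Long domains outside genes were few. Of the 6631 domains of at least 10 kb, 5 touched no annotated gene of any biotype, with a median length of 14.8 kb. The longest was 22.9 kb on chromosome 4 (91210935 to 91233795), 16.97 kb from Elavl2, an RNA-binding protein gene of neurons, and the next was 17.9 kb on chromosome 3 (17752681 to 17770594), 19.3 kb from the host gene of miR-124. Both replicates covered at least 50% of 2 of them, on chromosome 12 (108772470 to 108787295) and chromosome 17 (36273260 to 36283268). The fifth lay on chromosome 14 (56708675 to 56719503), 1.21 kb past the end of Pspc1. In the RefSeq annotation of the same build 3 of the 5 touched a gene, and a longer Elavl2 model held 97.4% of the domain near Elavl2. The number of domains was 9 in the pooled list, 8 in replicate 2's own list, 2 with gaps of up to 1 kb and 10 with gaps of up to 10 kb.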

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

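The test of whether long domains outside genes continue a marked gene was chosen only after the domains were seen. The patterns weighed below were noticed in the data, and the other tests had their possible outcomes written down before they were run.

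Signal lay outside the lists and sequences compared above. Of the peaks on sequences not placed on the chromosomes, replicate 1 held 14, replicate 2 held 14 and the replicated list 8. The pooled list held 77297 peaks that were not in the replicated list, with a median width of 184 bp against 610 bp for those in it. Those on chromosomes had 90.3% of their bases in protein-coding gene bodies, and 33.6 and 36.4% of them had at least 50% of their length in peaks of replicate 1 and replicate 2.

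Neural progenitor genes were more covered in replicate 2 than matched genes, with more coverage there in 38 of 42 genes with a mean coverage of at least 5%. Most genes shared this direction, 6043 of 7663 marked genes among them. Lists that did not differ from matched lists had counts as high, such as spliceosome genes (34 of 36) and translation factors (47 of 50). The count alone thus does not set neural progenitor genes apart. Their median difference, replicate 1 minus replicate 2, was -8.47 points against -3.02 in lists matched on coverage and gene length (adjusted p = 0.0038, permutation test) and -2.13 in lists matched on coverage and GC content (adjusted p = 0.0019, permutation test), which argues against these as the whole cause. Early neuron genes differed the other way, by 1.24 against -1.59 in lists matched on coverage and length, an excess of 2.83 points (adjusted p = 0.0076, permutation test), with 13 of 29 genes higher in replicate 2. Each p here, and for the X- and Y-linked genes below, compares genes with other genes of the same 2 libraries. None of them measures variation between pools, since each pool has 1 library. A different balance of progenitors and neurons in the 2 pools may contribute, but this hypothesis was found and tested on the same 2 libraries, without an independent test. Cell cycle and dorsoventral patterning genes also differed under both matchings (-6.34 against -3.19 and -8.32 against -2.02 with length), 4 of 19 lists in all, and depth and batch, which the labels do not give, stay open.

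Among X-linked genes with a mean coverage of at least 5%, 203 of 244 were more covered in replicate 2, with a median difference of -5.06 points. By this count the autosomes ran from 549 of 830 genes (chromosome 7) to 224 of 273 (chromosome 18), so the count alone sets X little apart. Autosomal lists matched on coverage and length had -1.38 and those matched on coverage and GC content -2.23 (p = 2e-04 for each, the smallest these permutation tests can give), so neither accounts for the whole difference. The Y-linked genes Ddx3y (5.83 and 23.0% in replicates 1 and 2), Eif2s3y (0 and 13.6%), Kdm5d (3.31 and 19.3%) and Uty (0.764 and 4.999%), named in advance of their test, differed by a mean of -12.7 points against 0.0571 in matched autosomal genes (p = 2e-04, the smallest this permutation test can give). More male embryos in the pool of replicate 2 could give the Y-linked values, as a hypothesis, but whether they would also raise X-linked coverage was not tested, so the X-linked difference stays open. Autosomes departed from matched genes by -1.06 (chromosome 3) to 1.06 (chromosome 7) points, with adjusted p under the threshold for chromosomes 1, 3, 5, 7 and 14, and the cause was not tested.

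The 5 long domains outside genes were set against 3 explanations. Genes missing from the annotation used may account for part of them, since 3 touch a RefSeq gene, namely Elavl2, Gm30340 and Gm40573. The 5 had a median soft-masked share of 25.03%, at percentile 55.1 of the domains that touch genes. This argues against repeat sequence only as a shared account of all 5, since single domains ran from 12.6 to 57.9%. Repeat sequence stays open for the domain on chromosome 3 (57.9%, above the 95th percentile of 39.5%) and for that on chromosome 12 (34.4%, above the 75th percentile of 29.97%). A marked gene ends within 10 kb upstream of 1 of them, next to Pspc1. Domains that touch a gene were left out beforehand, so coverage joined to the end of a marked gene could not be counted. This count therefore cannot decide on continuation past a marked gene for the 5 as a set. No gene of the annotation used ended within 10 kb upstream of the domains on chromosomes 3 and 4. The domains on chromosomes 12 and 17 lie 2.74 and 0.958 kb past the ends of Gm34220 and H2-M10.2, which were not marked. Continuation past an unmarked gene was not tested. The domain on chromosome 4 lies 16.97 kb past the end of Elavl2 in the annotation used, but 97.4% of it lies within the longer RefSeq model of Elavl2. The domain on chromosome 17 (36273260 to 36283268) remains without an account among the explanations tested.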

How the results depend on the processing

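The shifts beyond the first 3 Mb of each chromosome were chosen only after the data were seen; all other alternatives were planned. Of 420 recomputed values of 51 results that answer a comparison, 378 kept their direction and side of the threshold or, without a test, stayed within the replicate spread or, for counts, within 1.5 times the count reported. Of the others, 19 moved beyond these limits (10 up, 9 down), 20 passed a threshold they had not passed, 2 no longer passed it and 1 reversed. Some of the values kept could hardly have changed. Erythroid, posterior Hox and olfactory receptor genes, for instance, had medians and matched medians of 0. The direction of the percents of shared peaks could not reverse either. The number kept therefore overstates how stable the results are. Of 936 values of 156 named genes, 826 stayed within the spread and 110 moved, 72 up and 38 down. The cause was not tested unless given.

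Marked genes (7663) numbered 9276 and 5167 at thresholds of 10 and 50%, 7814 without the first 1 kb, 6838 among genes of at least 5 kb, 5368 among genes that overlap no other, 8091 with pooled peaks and 7442 to 7631 with each replicate alone. Domains of at least 10 kb (6631) numbered 5410 and 6557 with gaps of up to 1 and 10 kb. Matching on exon number too left 9 lists above, with spliceosome genes at 49.3 points over matched lists against 72.9 and cell cycle genes at 55.2 against 73.1.

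With −log10 p of at least 5, replicate 1 held 129186 peaks over 135 Mb and replicate 2 held 115671 over 151 Mb, fewer by construction, the share of genes with more coverage in the 3' part was 87.0% and the X to autosome ratio 0.262. With −log10 q of at least 2 that share was 87.8%. It was 84.0% for genes of at least 30 kb, 89.3% for the last against the first part of 3, 89.5% for genes with no other within 10 kb, and 87.9595 to 88.0451% with each replicate alone. With 50% of both peaks overlapping, 36.7% of replicate 1's and 43.8% of replicate 2's peaks were shared. Random placement gave folds of 2.31 in gene bodies and 0.0899 outside genes, with p = 0.0952, the smallest that 20 draws of this permutation test allow. Domains outside genes numbered 9 in the pooled list, 2 with gaps of up to 1 kb, 10 with gaps of up to 10 kb, and 7 to 8 with each replicate alone.

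Lists below matched genes numbered 0 to 2 with each replicate alone. Mature neuron (-3.94) and long neuronal genes (-0.587) passed in replicate 1 alone and had -3.61 and -0.390 in replicate 2. With pooled peaks 1 list was below, mature neuron (-5.23). Among genes of at least 5 kb 1 list was below, vomeronasal receptors (-8.79), and clustered protocadherins reversed to 37.2, where members that share covered bases are counted separately. With the share of marked genes 16 lists were below, in points: endothelium -36, erythroid -33.3, forebrain and midbrain -34.4, germline -34.3, heart and muscle -32.9, dorsoventral patterning -19.4, liver -37.9, macrophage -26.1, mature neuron -27.8, mesenchyme -30, neural crest -22.7, olfactory receptors -34.7, oligodendrocyte and astrocyte -27.3, posterior Hox -29.5, histones -9.70 and vomeronasal receptors -34.7. Depth is unknown, so a gene without peaks is one in which no peak was called.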

Other observations

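The comparisons by exon number and of Zfp genes along the gene were chosen only after the data were seen.

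Among protein-coding genes of like length, olfactory and vomeronasal receptors left out, genes with more exons were marked more often. At 1 to 3 kb, 10.6% ± 0.467 (SD, n = 2) of 606 single-exon genes were marked, 15.8% ± 0.995 of 711 genes with 2 to 3 exons and 35.0% ± 1.499 of 283 genes with 4 to 9 exons. At 10 to 30 kb the shares were 24.8% in both replicates for 475 genes with 2 to 3 exons, 42.8% ± 0.364 for 3303 genes with 4 to 9 exons and 57.5% ± 0.545 for 2466 genes with 10 or more. No test was made.

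Zfp genes, which encode zinc finger proteins, were set beside other marked genes of the same length range, without a test of the difference. More coverage in the 3' part was found in 88.7% ± 0.697 (SD, n = 2) of 203 Zfp genes and 88.5% ± 0.0743 of 4756 others. The last 25% of the body was covered to 77.0% ± 1.83 in Zfp genes and 75.5% ± 2.42 in the others, and the 2 kb after the end to 46.5% ± 2.12 and 50.6% ± 2.07.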
